A study of Mus musculus with 8 samples.

How the data were processed

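Total RNA was sequenced from epidermis of mouse embryos in 8 libraries, 2 from each of 4 groups: control and knockout embryos at embryonic days 15.5 and 17.5 (E15.5 and E17.5). Per the series design text, mice with floxed Nir alleles were crossed to mice carrying Krt14-Cre, the epidermis was lifted from the dermis, and RNA was extracted with Trizol. Nir is the gene Noc2l. Per the series design text, reads were aligned to the mm10 mouse genome with TopHat2 and counted with HOMER, and the authors called differential genes with edgeR. The HOMER version, the strand setting, the treatment of reads that match several places, the read number and length, and the handling of isoforms are not given in the sources used here. Genes that overlap a neighbour on the opposite strand therefore cannot be separated from it with certainty.

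The values are whole-number counts of reads per RefSeq transcript, deposited by the authors with no normalization. The files held 30521 transcripts. A name was found for 29908 of them in the RefSeq gene table of GRCm38.p6 and for 182 more in GENCODE M21. The 431 transcripts without a name held 2.08% of all counts, from 1.43% to 2.68% per library, and were left out of library sizes and tests. A gene with several transcripts (4170 of 23146 genes) was represented by the transcript with the largest total, because summing transcripts that share exons would count a read more than once. This choice was made after the counts were seen, since gene-level counts had been planned for, and the sum was run as an alternative. Tables joining the libraries of a stage held the same counts (0 values differed) and were not used. Counts in near-identical copies cannot be assigned with certainty. This holds for the Skint, Serpinb3, Sprr2, Lce and hemoglobin families, for Krt6a and Krt6b, and for ribosomal protein genes, which have many processed copies.

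Tests were run on the raw counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 4 groups, which left 16342 genes. Libraries were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model with 1 mean per group was fitted to all 8 libraries, so that the groups shared the estimate of the spread. The contrasts were knockout against control at E15.5, the same at E17.5, the difference between these effects, and E17.5 against E15.5 in control epidermis. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Fold changes are log2 values from the fit. Their standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM values on TMM-scaled totals, as mean ± SD of 2 libraries. Where a group had 3 counts or fewer in all, the ratio is given with its 95% counting interval, which covers counting error only. The labels number the replicates but do not say whether they came from separate embryos, pools or litters, so the p-values measure the spread between these samples, which may be in part technical. With 2 libraries against 2, an exact permutation test of 1 value cannot go below p = 0.333, so none was used for single genes.

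Before the data were examined, the tests, the 24 gene lists, the alternatives and the rule for naming genes were fixed. The rule named Noc2l and the p53 family (Trp53, Trp63 and Trp73). It named the 8 risen and 8 fallen genes with the largest fold change in each knockout comparison and in the control comparison, among genes past the test with a mean log2 CPM of at least 1 over all libraries and no overlap between the groups. For each list with a called test or at least 3 called members it named up to 3 called members with the smallest adjusted p, and for the difference between stages the 5 genes in each direction with the smallest adjusted p. Loci known only by a clone or number were passed over. Genes chosen after their values were seen are said to be so. Some genes that the rule picks are not reported here.

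The lists cover p53 target genes, apoptosis, ribosome biogenesis, cytosolic ribosomal proteins, the cell cycle, basal, spinous and cornified keratinocytes, barrier lipids, periderm, hair follicles, stress keratins and alarmins, the amino acid response, and immediate early and heat shock genes. They also cover markers of dermal fibroblasts, endothelium, myeloid cells, T cells, melanocytes, Merkel cells, skeletal muscle, erythroid cells, and Schwann cells and neurons, which epidermal preparations can hold. Sex-linked genes form the last list, reported as values per library. The p53 and apoptosis lists share 6 genes, the p53 and amino acid response lists 1, and the stress list shares 2 each with the cornified and periderm lists. The 23 other lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison, and again with the correlation estimated from the data.

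Alternatives were other size factors, DESeq2 1.42.0, limma-voom, no filter on low counts and a stricter one (CPM of at least 1 in 4 libraries), only the groups compared, a replicate block, each library left out in turn, a fold threshold, fry in place of camera, and a higher expression minimum for the relation with development. After the data were seen, sums of transcripts, all transcripts tested singly, library totals as the only scaling and a term for sex were added. On simulated data with 200 changed genes, the test called 47.8% of 1.5-fold, 79.1% of 2-fold and 100% of 4-fold changes at E15.5 (16093 genes), and 47.8%, 88.1% and 100% at E17.5 (16079 genes). For the difference between stages it called 19.4%, 58.2% and 89.4% (16057 genes), and for the control comparison 34.3%, 83.6% and 95.5% (16064 genes). Calls among the unchanged genes numbered 10, 9, 4 and 7. The simulated libraries shared 1 mean profile apart from the 200 genes, changed equally often in each direction. The real knockout comparisons called 45.5% and 53.5% of genes, so these rates need not hold there. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for joins and plots. Coordinates are GRCm38, the build of mm10.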

Results

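The transcriptome of epidermis was measured in mouse embryos at E15.5, when the epidermis is stratifying, and at E17.5, when its barrier is being completed. The series title gives the aim, which is to learn what Noc2l (Nir) does in the developing epidermis. Noc2l encodes a protein that inhibits histone acetylation, binds p53 and takes part in making ribosomes. In the knockout embryos, Cre recombinase expressed from the promoter of keratin 14, a gene of basal keratinocytes, deletes the floxed Noc2l alleles, and embryos with floxed alleles served as controls. Each of the 4 groups had 2 libraries. Gene counts summed to 27115926 and 27012764 in the E15.5 control libraries, 28797281 and 28222677 in the E15.5 knockout libraries, 25226357 and 27779392 in the E17.5 control libraries and 28895657 and 28833998 in the E17.5 knockout libraries. Between 17835 and 18092 genes were detected per library. The most abundant transcript was Krt1 in all 4 control libraries, at 2.22% to 3.9% of counts, and Col1a1 in all 4 knockout libraries, at 2.74% to 3.73%. Replicates of a group correlated at 0.986 to 0.989 (Pearson, log2 CPM across genes). Replicates differed by more than sampling noise, with a chi-square per gene of 16.3 to 35.1. The first principal component held 77.0% of the variance and parted the genotypes, with scores of -64.7 to -48.7 in controls and 36.6 to 77.2 in knockouts. The next component held 13.3% and parted the stages.

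The targeted gene itself changed little. Noc2l lies on chromosome 4 from 156234655 to 156247616 (GRCm38, plus strand). Its level was 107 and 97.4 CPM in the E15.5 control libraries against 95.6 and 91.6 CPM in the E15.5 knockout libraries, and the log2 fold change of -0.12 ± 0.10 (SE, n = 2 per group) did not pass the test (edgeR, adjusted p = 0.33). At E17.5 it was 106 and 121 CPM in controls against 85.4 and 86.9 CPM in knockouts, and Noc2l fell, with a log2 fold change of -0.39 ± 0.10 (adjusted p = 0.0062). Without E17.5 control replicate 2 that change was -0.29 (adjusted p = 0.051). The difference between the effects at the 2 stages did not pass the test (-0.27 ± 0.14, adjusted p = 0.37). The counts cover the whole transcript and the labels do not say which exons are floxed, so the Noc2l level does not check the genotype labels, and libraries are named after their labels.

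At E15.5 the genes that keratinocytes use to stratify fell in knockout epidermis, together with those of hair placodes, while keratins of the periderm and markers of several other cell types rose. Krt1 and Krt10, the main keratins of the suprabasal layers, fell from 39432 ± 712 to 369 ± 52.1 CPM and from 35787 ± 2295 to 2572 ± 205 CPM (log2 fold changes -6.74 ± 0.33 and -3.80 ± 0.23, adjusted p = 5.4e-08 and 2.5e-07). Krt6a, a keratin of periderm and injured epidermis, rose from 46.6 ± 8.5 to 1562 ± 28.9 CPM (5.07 ± 0.18, adjusted p = 6.3e-09). In all, 3792 genes rose and 3639 fell, which is 45.5% of the 16342 genes tested, and 1434 and 1545 of them changed at least 2-fold.

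Among genes with a mean log2 CPM of at least 1, those with the largest falls at E15.5 included the cornified envelope protein gene Flg2 (-8.03 ± 0.37, from 1071 to 4.10 CPM) and Serpinb3a (-8.02 ± 0.25), Serpinb3b (-7.87 ± 0.25) and Serpinb3c (-9.56 ± 0.42), which encode serine protease inhibitors. Skint3 (-8.16 ± 0.39) and Skint9 (-8.08 ± 0.49), of a family expressed in skin and thymus, fell likewise, as did Ano7 (-8.48 ± 0.31) and Atp6v1b1 (-7.66 ± 0.32), which encodes a subunit of the vacuolar proton pump. The largest rises besides Krt6a were in its near-identical neighbour Krt6b (4.86 ± 0.21), the tight junction gene Cldn3 (5.26 ± 0.32), the BMP antagonist gene Grem1 (4.31 ± 0.38), the tenascin gene Tnn (4.15 ± 0.30), Dynap (3.91 ± 0.24), the matrix phosphoprotein gene Spp1 (3.88 ± 0.52) and the embryonic hemoglobin gene Hba-x (4.20 ± 0.85). Hba-x stood at 215 CPM in knockout replicate 1 and 22.9 CPM in knockout replicate 2, and its change was 1.82 without the former and 5.06 without the latter. Sizes also moved by more than 1.5 times when a library was left out for other genes with few counts in a group. Without E15.5 knockout replicate 1 the change was -10.37 for Serpinb3c, -9.37 for Ano7, -10.24 for Skint3 and -7.14 for Skint9. Without E15.5 knockout replicate 2 it was -7.31 for Skint3, -12.71 for Skint9, which then had 0 knockout counts and a size set by the prior count, and 3.14 for Spp1, and without E15.5 control replicate 2 it was 4.95 for Grem1. All of these calls held.

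The keratinocyte lists fell at every layer. Of 15 basal genes, 13 fell and 1 rose (median log2 fold change -1.91, camera adjusted p = 1.5e-22). Examples are Col17a1 (-3.37 ± 0.11) and Lamb3 (-3.70 ± 0.13), which anchor basal cells to the basement membrane, and the P-cadherin gene Cdh3 (-2.76 ± 0.12). All 20 spinous genes fell (median -1.63, adjusted p = 2.2e-18, and adjusted p = 0.073 with an estimated correlation), among them the desmosomal cadherin gene Dsg1a (-3.80 ± 0.18). Of 37 cornified envelope and granular layer genes, 31 fell and 3 rose (median -2.02, adjusted p = 5.3e-19, and adjusted p = 0.15 with an estimated correlation), with the transglutaminase gene Tgm3 at -5.69 ± 0.18 and the involucrin gene Ivl at -5.94 ± 0.27. Of 21 barrier lipid genes, 18 fell (median -1.48, adjusted p = 6.9e-15, and adjusted p = 0.12 with an estimated correlation), including the lipoxygenase gene Alox12e (-6.70 ± 0.29) and the ceramidase gene Acer1 (-5.08 ± 0.24). Counts of risen and fallen members adjusted over the list alone were the same for these 4 lists. Dermal fibroblast markers rose in the same libraries (median 1.23).

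Hair placode and follicle genes had the lowest median of all lists at E15.5. Of 24 members, 23 fell and 1 rose (median -3.24, adjusted p = 3.3e-32), and the count adjusted over the list alone was the same. Shh, the placode morphogen, fell from 26.8 ± 0.98 to 0.254 ± 0.060 CPM (-6.70 ± 0.21). Lhx2, a transcription factor of follicle progenitors, changed by -5.88 ± 0.19. The calls of the basal and follicle lists held with an estimated correlation (adjusted p = 0.044 and 0.014), and those of the 13 other lists called at E15.5 did not. Markers of Merkel cells, touch receptors of epithelial origin, also fell, 5 of 7 with 1 risen and the same count adjusted over the list alone (median -3.09, adjusted p = 0.038, and adjusted p = 0.18 with an estimated correlation). They include the granin gene Chga (-6.57 ± 0.34) and Sox2 (-3.09 ± 0.33), while the mechanosensory channel gene Piezo2 rose (1.34 ± 0.13). The call of the Merkel list was lost without E15.5 knockout replicate 1 (adjusted p = 0.081) or 2 (0.069), without E17.5 control replicate 1 (0.093) or 2 (0.093), and without E17.5 knockout replicate 1 (0.071) or 2 (0.068). It was also lost with no filter on low counts (0.063), the stricter filter (0.064), only the groups compared (0.091) and a term for sex (0.0504).

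Keratins of the periderm, the transient outer layer of embryonic epidermis, rose. Of 10 periderm genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone; median 1.91, adjusted p = 6.6e-06, and adjusted p = 0.18 with an estimated correlation). Besides Krt6a, Krt8 (2.99 ± 0.15) and Krt18 (2.22 ± 0.14) rose, the keratin pair of simple epithelia. Stress keratins and alarmins went both ways, with 7 of 17 risen and 5 fallen (the same adjusted over the list alone), and the list did not pass (median 0.35, adjusted p = 0.14). The cystatin gene Stfa1 fell (-3.99 ± 0.13) where Krt6a and Krt6b rose.

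The p53 family fell at E15.5. Trp63, which encodes the transcription factor p63 that keratinocytes need to stratify (chromosome 16, 25683763 to 25892088), fell from 222 ± 16.6 to 17.4 ± 3.5 CPM (-3.67 ± 0.16, adjusted p = 2.9e-08). Trp73 (chromosome 4, 154056249 to 154139875) changed by -4.53 ± 0.19, and Trp53 itself (chromosome 11, 69580348 to 69591873) by -0.56 ± 0.10 (adjusted p = 0.00076). Of 40 p53 target genes, 17 rose and 6 fell (the same adjusted over the list alone; median 0.31, adjusted p = 0.015, and adjusted p = 0.20 with an estimated correlation). The sulfatase gene Sulf2 (1.89 ± 0.13) and the apoptosome gene Apaf1 (1.10 ± 0.10) rose, while Perp, which p63 also drives in epidermal desmosomes, fell (-2.35 ± 0.14). In the same libraries fibroblast (median 1.23) and myeloid markers (1.17) rose and basal keratinocyte genes fell (-1.91). Of 24 apoptosis genes, 10 rose and 3 fell (the same adjusted over the list alone; median 0.29, adjusted p = 0.088), with Pmaip1 at 1.33 ± 0.21 and Casp2 at -0.74 ± 0.13.

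Of the lists of protein synthesis and growth, only ribosomal proteins passed camera at E15.5. In these libraries basal keratinocyte genes fell (median -1.91) and fibroblast (1.23) and erythroid markers (2.74) rose. Of 76 cytosolic ribosomal protein genes, 34 fell and 0 rose (35 fallen adjusted over the list alone; median -0.46, adjusted p = 0.0033, and adjusted p = 0.42 with an estimated correlation), including Rpl36 (-0.89 ± 0.12) and Rps3a1 (-0.62 ± 0.11). Of 40 ribosome biogenesis factors, 15 fell and 0 rose, with Nhp2 at -0.85 ± 0.12 and Dkc1, the RNA pseudouridine synthase, at -0.65 ± 0.11. Of 32 cell cycle genes, 10 fell and 1 rose, with Ccnb1 at -0.76 ± 0.12, Mcm7 at -0.53 ± 0.11 and Ccne1 at 0.65 ± 0.15. The biogenesis and cell cycle lists did not pass (adjusted p = 0.053 and 0.072; medians -0.27 and -0.27). The same holds for the amino acid response list (4 of 18 risen, 9 fallen; median -0.38, adjusted p = 0.061), in which the serine synthesis genes Phgdh (-2.15 ± 0.11) and Psat1 (-1.83 ± 0.12) fell and the folate enzyme gene Aldh1l2 rose (1.29 ± 0.13). It holds too for immediate early and heat shock genes (1 of 13 risen, 6 fallen; median -0.51, adjusted p = 0.072), in which Hspa1b (-1.93 ± 0.14) and Hspa1a (-1.57 ± 0.16) fell. Counts adjusted over the list alone were the same for these lists except the amino acid response list, with 5 risen.

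Markers of cells outside the keratinocyte lineage rose in E15.5 knockout libraries by unequal amounts. Erythroid markers moved most, with 9 of 10 risen (10 adjusted over the list alone). Their median was 2.74 (camera adjusted p = 9.1e-08), and Hba-a1 went from 2585 ± 637 to 17300 ± 6141 CPM. Some members are near-identical copies with nearly equal counts, such as Hba-a1 and Hba-a2 (21642 and 21647 CPM in E15.5 knockout replicate 1). In every comparison this list therefore holds fewer separate signals than members. All 14 dermal fibroblast markers rose (median 1.23, adjusted p = 6.9e-09), such as the fibrillin gene Fbn1 (1.56 ± 0.16), Dpt (1.43 ± 0.15) and Col5a1 (1.42 ± 0.16). So did all 10 endothelial markers (median 0.62, adjusted p = 0.00036), with Tek at 1.28 ± 0.13 and Cdh5 at 0.75 ± 0.10. Of 11 myeloid markers, 10 rose (11 adjusted over the list alone; median 1.17, adjusted p = 8.4e-08), with the macrophage receptor gene Csf1r at 1.23 ± 0.12. Of 9 melanocyte markers, 7 rose (median 0.76, adjusted p = 2.0e-04), with Kit at 0.76 ± 0.11, and of 11 muscle markers 8 rose (11 adjusted over the list alone; median 0.59, adjusted p = 0.015), with Actc1 at 0.78 ± 0.15. Counts adjusted over the list alone were otherwise the same. With an estimated correlation the adjusted p was 0.18 for erythroid, 0.15 for fibroblast, 0.11 for endothelial, 0.099 for myeloid, 0.20 for melanocyte and 0.42 for muscle markers. The muscle call was lost without E15.5 control replicate 2 (adjusted p = 0.060). Schwann cell and neuron markers went both ways (4 of 9 risen, 3 fallen, and 6 and 3 adjusted over the list alone; median 0.73, adjusted p = 0.28), with Gap43 at 1.47 ± 0.15 and Stmn2 at -1.71 ± 0.23. T cell markers did not pass (2 of 7 risen, 1 fallen, the same adjusted over the list alone; median 0.14, adjusted p = 0.66), and Thy1, which fibroblasts and neurons also express, was among the risen (0.76 ± 0.14).

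**Figure D1:**
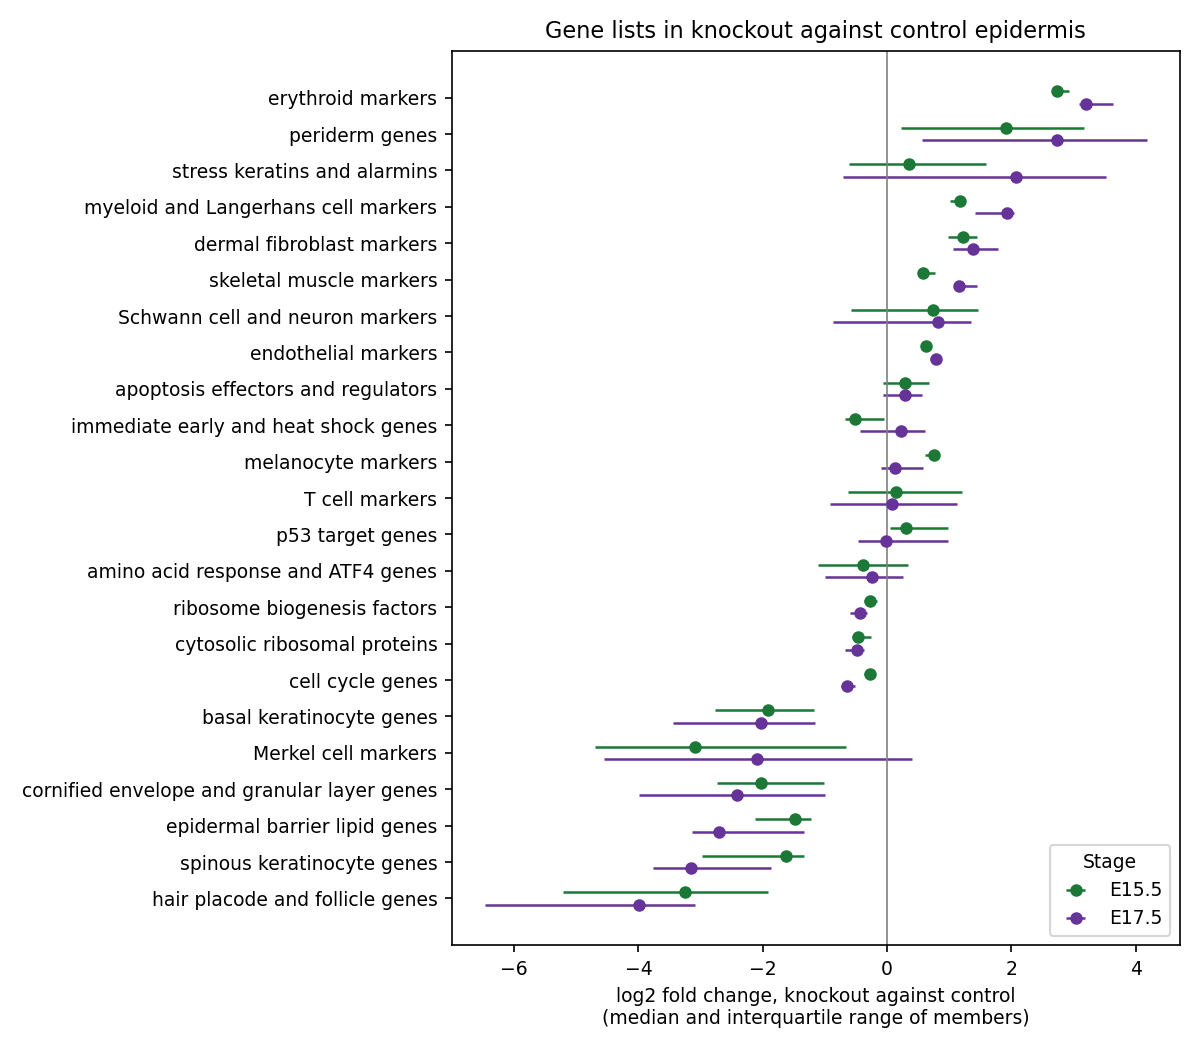
Median log2 fold change (knockout against control, horizontal axis) of the measured members of 23 gene lists, with the interquartile range of the members as a bar, at E15.5 (green) and E17.5 (purple). Follicle genes had medians of -3.24 and -3.98, and erythroid markers of 2.74 and 3.20.

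At E17.5 the same groups of keratinocyte and follicle genes fell in knockout epidermis, and periderm genes rose. Krt10 fell from 19759 ± 3206 to 372 ± 103 CPM (-5.73 ± 0.25, adjusted p = 1.3e-08). Krt15, a keratin of basal and follicle progenitor cells, fell from 862 ± 114 to 19.8 ± 2.8 CPM (-5.44 ± 0.19, adjusted p = 3.2e-09), and Krt18 rose from 0.911 ± 0.20 to 77.8 ± 5.2 CPM (6.42 ± 0.18, adjusted p = 1.6e-09). In all, 4371 genes rose and 4364 fell (53.5% of those tested), 2192 and 1774 of them at least 2-fold. With library totals as the only scaling, an alternative added after the data were seen, 3295 rose and 6284 fell, and the median of all genes was -0.23, so changes of that size depend on the scaling.

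Among genes with a mean log2 CPM of at least 1, the largest rises at E17.5 were in genes nearly silent in the controls. Dynap had 1 count in the control libraries and 2042 in the knockout libraries, a ratio of 2172 (counting interval 389 to 85844), and Psca, a cell surface gene of bladder and stomach epithelium (chromosome 15, 74714839 to 74717065), had 3 and 2004 counts, a ratio of 711 (243 to 3449). Serpinb9b (8.52 ± 0.49), Sprr3 (6.99 ± 0.67), the mesothelin gene Msln (6.25 ± 0.39) and the uroplakin genes Upk3bl (6.15 ± 0.48) and Upk3b (5.71 ± 0.40) followed. Each of these genes, Dynap and Psca included, was lower in E17.5 than in E15.5 control libraries. Apart from Serpinb9b, each was also lower in E17.5 than in E15.5 knockout libraries. Without E17.5 control replicate 2 the change was 12.97 for Dynap, set by the prior count since 0 control counts are left, 9.35 for Serpinb9b, 8.02 for Sprr3 and 6.91 for Upk3bl, and without E17.5 control replicate 1 it was 9.98 for Dynap and 6.52 for Upk3b. The largest falls above the same minimum were in hair follicle keratins, Krt28 (-8.15 ± 0.30), Krt71 (-7.94 ± 0.46), Krt25 (-7.54 ± 0.37) and Krt73 (-7.15 ± 0.45), in Shh (-8.07 ± 0.22), Atp6v1b1 (-7.06 ± 0.28), Chga (-6.78 ± 0.35) and the nucleotide receptor gene P2ry4 (-6.92 ± 0.55). Without E17.5 knockout replicate 1 the change was -9.37 for Krt28, -10.05 for Krt71, -8.39 for Krt25, -7.86 for Krt73 and -11.03 for P2ry4, which then had 0 knockout counts, and without replicate 2 it was -7.51 for Krt28, -7.13 for Krt71 and -5.97 for P2ry4. All of these calls held.

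Every keratinocyte layer was lower at E17.5. Of 15 basal genes, 13 fell and 2 rose (median -2.03, adjusted p = 1.9e-20), with Cdh3 at -4.00 ± 0.13 and Col17a1 at -3.46 ± 0.11. Of 20 spinous genes, 19 fell (median -3.15, adjusted p = 1.1e-22, and adjusted p = 0.052 with an estimated correlation), with Dsg1a at -5.25 ± 0.19 and the differentiation regulator Zfp750 at -3.58 ± 0.16. Of 37 cornified and granular genes, 27 fell and 5 rose (6 risen adjusted over the list alone; median -2.41, adjusted p = 1.8e-18, and adjusted p = 0.18 with an estimated correlation), with Tgm3 at -5.90 ± 0.18, the protease gene Klk5 at -4.16 ± 0.14 and the envoplakin gene Evpl at -3.99 ± 0.15. Of 21 barrier lipid genes, 18 fell and 2 rose (median -2.70, adjusted p = 5.8e-16, and adjusted p = 0.14 with an estimated correlation), with Alox12e at -6.07 ± 0.24, Acer1 at -6.02 ± 0.28 and the triglyceride synthesis gene Dgat2 at -2.70 ± 0.13. Acer1 changed by -6.88 without E17.5 knockout replicate 1. Counts adjusted over the list alone were otherwise the same. Fibroblast markers stood above control in the same libraries (median 1.39).

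Of 24 follicle genes, 23 fell and 0 rose at E17.5, the same adjusted over the list alone (median -3.98, adjusted p = 4.7e-40), among them the inner root sheath genes Krt27 (-8.10 ± 0.26) and Tchh (-4.65 ± 0.14). The calls of the basal and follicle lists held with an estimated correlation (adjusted p = 0.046 and 0.0051), and those of the 13 other lists called at E17.5 did not. Merkel cell markers did not pass as a list (2 of 7 risen, 3 fallen, and 2 and 4 adjusted over the list alone; median -2.09, adjusted p = 0.26), although Sox2 fell (-2.34 ± 0.32) and Piezo2 rose (1.59 ± 0.13). Of 10 periderm genes, 8 rose and 2 fell (the same adjusted over the list alone; median 2.73, adjusted p = 1.6e-06, and adjusted p = 0.22 with an estimated correlation), with Krt6a at 5.09 ± 0.18 and Krt8 at 4.36 ± 0.16. Stress keratins and alarmins rose at this stage, 11 of 17 with 4 fallen (the same adjusted over the list alone; median 2.08, adjusted p = 0.0080, and adjusted p = 0.35 with an estimated correlation). That call was lost without E17.5 control replicate 2 (adjusted p = 0.093). Within the list Krt6b rose (3.79 ± 0.20) and Stfa1 fell (-4.34 ± 0.13). The mean log2 CPM of the list was 3.42 and 3.51 in E15.5 controls and 2.66 and 2.63 in E17.5 controls. In knockouts it was 4.04 and 3.91 at E15.5 and 3.78 and 4.19 at E17.5. Controls were thus lower at E17.5, while knockout levels overlapped between the stages.

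Trp63 fell from 217 ± 25.9 to 10.8 ± 1.8 CPM at E17.5 (-4.33 ± 0.17, adjusted p = 5.8e-09), Trp73 changed by -6.06 ± 0.23 and Trp53 by -0.44 ± 0.10 (adjusted p = 0.0028). The p53 target list did not move as a whole (14 of 40 risen, 11 fallen, the same adjusted over the list alone; median -0.02, adjusted p = 0.80). Within it Apaf1 rose (1.18 ± 0.10), while Perp (-4.01 ± 0.15) and Ei24 (-1.06 ± 0.10) fell. Of 24 apoptosis genes, 10 rose and 3 fell (the same adjusted over the list alone; median 0.30, adjusted p = 0.26), with Casp2 (-0.99 ± 0.13) and Bcl2 (-0.88 ± 0.12) among the fallen.

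Genes of protein synthesis and the cell cycle fell at E17.5, in libraries where basal keratinocyte genes fell (median -2.03) and fibroblast (1.39) and erythroid markers (3.20) rose. Of 40 ribosome biogenesis factors, 31 fell and 0 rose (33 fallen adjusted over the list alone; median -0.44, adjusted p = 0.0013, and adjusted p = 0.42 with an estimated correlation), with Dkc1 at -1.17 ± 0.11 and Nhp2 at -1.10 ± 0.12. Of 76 ribosomal protein genes, 44 fell and 0 rose (47 fallen adjusted over the list alone; median -0.48, adjusted p = 0.0028, and adjusted p = 0.42 with an estimated correlation), with Rps3 at -0.70 ± 0.12 and Rps3a1 at -0.63 ± 0.11. Of 32 cell cycle genes, 30 fell and 0 rose (the same adjusted over the list alone; median -0.64, adjusted p = 0.00015, and adjusted p = 0.42 with an estimated correlation), with Ccnb1 at -1.13 ± 0.12 and the kinetochore gene Cenpf at -0.99 ± 0.12. The amino acid response list (4 of 18 risen, 7 fallen, and 4 and 8 adjusted over the list alone; median -0.23, adjusted p = 0.21) and the immediate early and heat shock list (3 of 13 risen, 3 fallen, the same adjusted over the list alone; median 0.23, adjusted p = 0.95) did not pass. Phgdh (-2.17 ± 0.12) and Psat1 (-1.77 ± 0.12) fell and Aldh1l2 rose (1.28 ± 0.13), and Hspa1b (-2.01 ± 0.15) and Hspa1a (-1.24 ± 0.16) fell while Ier3 rose (1.08 ± 0.13).

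Markers of other cell types rose again at E17.5. All 11 myeloid markers rose (median 1.93, adjusted p = 3.1e-13), with the lysozyme gene Lyz2 from 20.4 ± 0.32 to 109 ± 8.2 CPM (2.41 ± 0.12). Of 10 erythroid markers, 8 rose (median 3.20, adjusted p = 1.6e-06), with Hba-a1 at 3.65 ± 0.27 and the heme synthesis gene Alas2 at 3.62 ± 0.29. Of 14 fibroblast markers, 13 rose (median 1.39, adjusted p = 3.0e-08), with Col1a2 from 6707 ± 368 to 23214 ± 983 CPM, Col5a1 at 1.89 ± 0.16 and Fbn1 at 1.80 ± 0.16. All 10 endothelial markers rose (median 0.80, adjusted p = 0.00048), with Tek at 1.44 ± 0.13 and Cdh5 at 0.85 ± 0.10, and all 11 muscle markers rose (median 1.16, adjusted p = 0.00014), with Actc1 at 1.48 ± 0.15 and Ckm at 1.09 ± 0.17. The adjusted p with an estimated correlation was 0.052 for myeloid, 0.27 for erythroid, 0.16 for fibroblast, 0.13 for endothelial and 0.35 for muscle markers. Melanocyte markers (3 of 9 risen; median 0.13, adjusted p = 0.26) and Schwann cell and neuron markers (5 of 9 risen, 3 fallen; median 0.83, adjusted p = 0.31) did not pass, although Kit (0.66 ± 0.11), Sox10 (0.57 ± 0.12) and Gap43 (1.38 ± 0.15) rose. T cell markers did not pass either (2 of 7 risen, 2 fallen; median 0.08, adjusted p = 0.95), with Thy1 at 0.70 ± 0.14. Counts adjusted over the list alone were the same except for T cell markers, with 3 risen and 3 fallen.

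**Figure D2:**
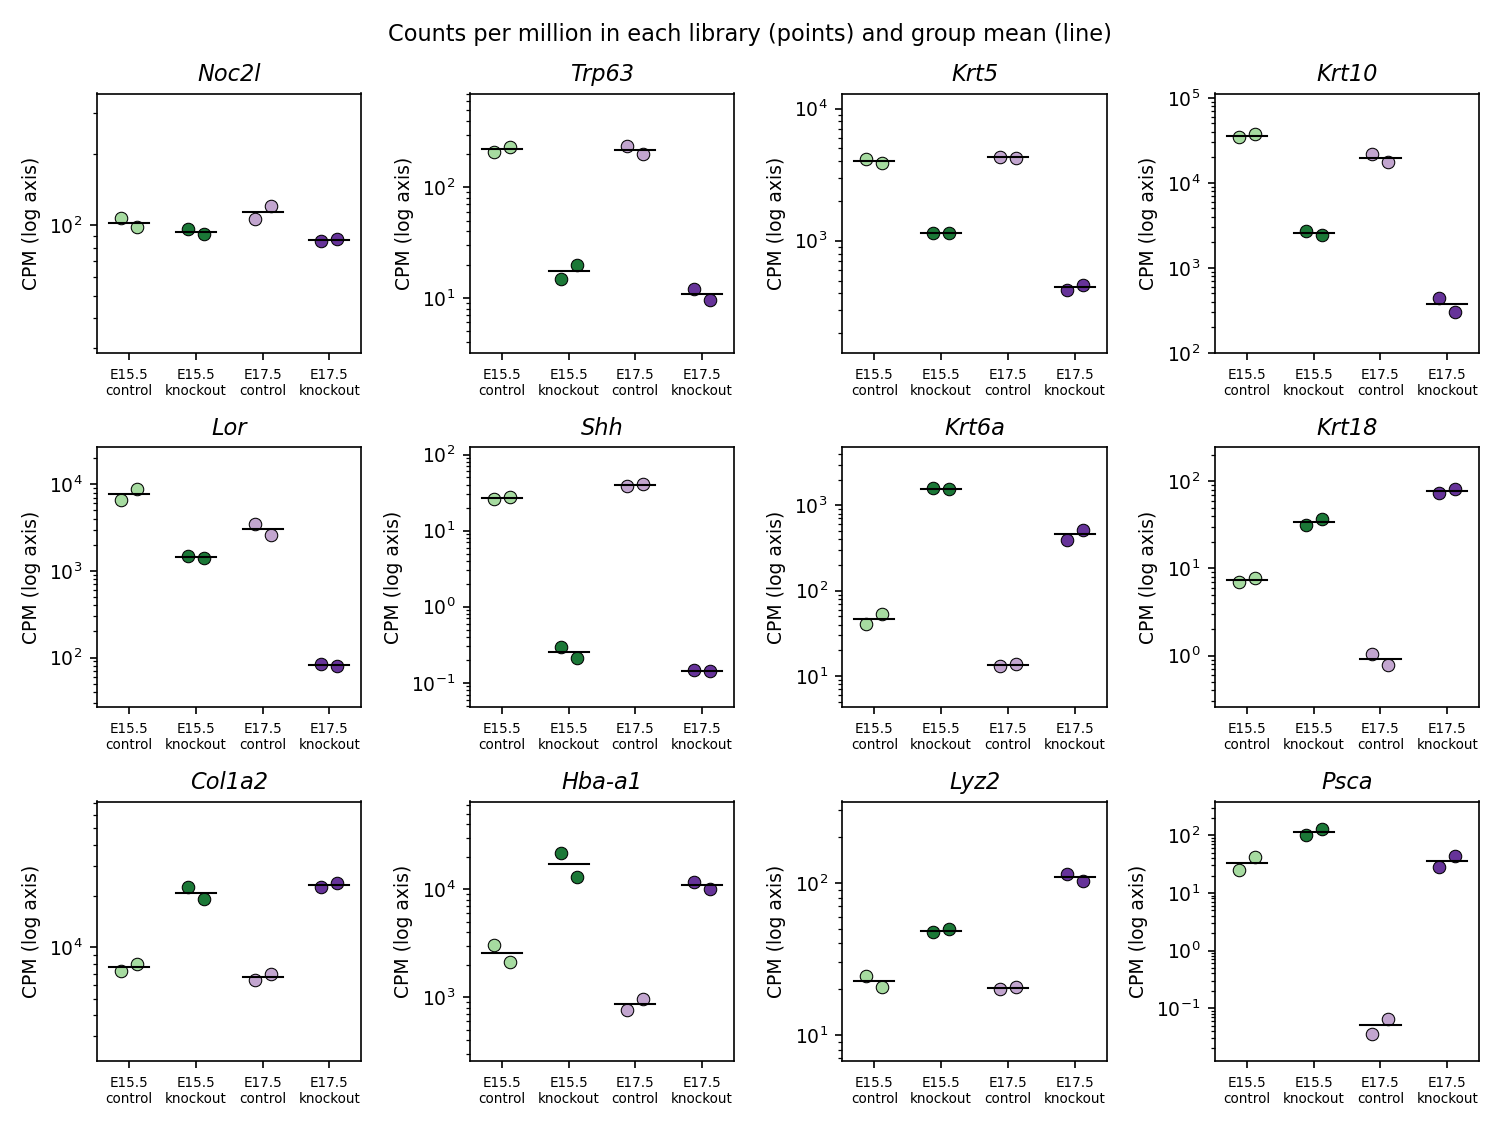
CPM (log axis) of 12 genes in each library (points) with the group mean (line) for the 4 groups. Noc2l differed little between groups, Trp63, Krt5, Krt10, Lor and Shh were lower in both knockout groups, and Krt6a, Krt18, Col1a2, Hba-a1, Lyz2 and Psca were higher.

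Much of the knockout response was shared by the stages. Of the genes tested at both, 3181 rose at both stages, where independent lists of those lengths would share 1014, and 2934 fell at both, where 972 would be shared. Only 46 genes passed in opposite directions. Across all 16342 genes the log2 fold changes of the stages correlated at r = 0.80 (Spearman rho 0.82). Genes are not independent replicates, so no p-value is attached. The stages have separate control libraries.

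The sizes of the knockout effects did differ between stages for 711 genes, called by the interaction contrast. The effect was more positive at E17.5 for 308 genes and more negative for 403. The genes named next have the smallest adjusted p in each direction among genes with a mean log2 CPM of at least 1. They need not have the largest differences. With a positive difference they were Krt18 (difference 4.20 ± 0.23, adjusted p = 5.7e-06), the kallikrein gene Klk6 (3.57 ± 0.28, adjusted p = 0.00011), the chemokine gene Ccl6 (3.11 ± 0.27), Psca (7.55 ± 0.65, a fitted value that depends on the prior count, with 3 counts in E17.5 controls) and Upk3b (5.26 ± 0.49). Psca and Upk3b were lower at E17.5 than at E15.5 in both genotypes, more so in controls. Klk6 went from 1.24 to 2.24 CPM at E15.5 and from 2.70 to 57.9 CPM at E17.5. Ccl6 reversed. It stood at 14.7 and 20.3 CPM in the E15.5 control libraries and fell to a mean of 7.17 CPM (-1.29 ± 0.19, adjusted p = 0.00022), and it rose from 8.31 to 29.4 CPM at E17.5 (1.82 ± 0.19). Upk3b had a difference of 6.07 without E17.5 control replicate 1. At the negative end stood Tchh (-3.79 ± 0.19, adjusted p = 3.6e-06), the epidermal transcription factor gene Dlx3 (-3.32 ± 0.17), Krt15 (-3.88 ± 0.23), Serpinb7 (-3.30 ± 0.21) and the aldehyde oxidase gene Aox4 (-4.11 ± 0.29). Krt15 fell to 249 CPM at E15.5 and to 19.8 CPM at E17.5 from 735 and 862 CPM.

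Keratinocyte lists tested further below control at E17.5 than at E15.5 at the preset correlation, but none of these calls held with an estimated correlation (adjusted p = 0.19 for spinous, 0.41 for barrier lipid, 0.46 for cornified, 0.096 for follicle, and 0.41 for basal and for periderm genes). Of 20 spinous genes, 8 differed downward and 1 upward (median difference -0.57, camera adjusted p = 6.2e-09), with Zfp750 at -2.17 ± 0.21, Dmkn at -2.00 ± 0.22 and Krtdap at -1.78 ± 0.23. Barrier lipid genes (5 of 21 downward, 2 upward; median -0.94, adjusted p = 0.00022), cornified and granular genes (11 of 37 downward, 4 upward; median -0.22, adjusted p = 0.00022) and follicle genes (8 of 24 downward, 1 upward; median -0.51, adjusted p = 2.8e-10) differed in the same direction. The loricrin gene Lor (-2.78 ± 0.25), Klk5 (-2.01 ± 0.18) and Evpl (-1.93 ± 0.18) are cornified examples, Cyp4f39 (-2.03 ± 0.32) and Alox12b (-1.98 ± 0.33) lipid examples, and Krt27 (-5.67 ± 0.57) and Msx2 (-2.95 ± 0.30) follicle examples. The mean log2 CPM of the follicle list was 4.45 and 4.33 in E15.5 controls and 5.43 and 5.42 in E17.5 controls. In knockouts it was 0.970 and 1.25 at E15.5 and 1.12 and 0.788 at E17.5. In the basal list 3 of 15 genes differed downward, Krt15, Krt5 (-1.45 ± 0.18) and Cdh3 (-1.24 ± 0.17), and 1 upward. Its test was downward (adjusted p = 0.0061) while its median was 0.04. Periderm genes tested upward (3 of 10, camera adjusted p = 0.0016) with a median of -0.04. They were led by Krt18, Krt13 (2.99 ± 0.43) and Krt8 (1.36 ± 0.21). Krt13 was lower at E17.5 in both genotypes, more so in controls. It went from 76.3 and 109 to 2.54 and 3.53 CPM in controls, and from 122 and 171 to 26.4 and 50.3 CPM in knockouts. Adjusted over the list alone, the genes upward and downward numbered 2 and 9 for spinous, 4 and 11 for barrier lipid, 7 and 12 for cornified, 1 and 8 for follicle, 2 and 4 for basal and 3 and 1 for periderm genes. The cornified call was lost without E17.5 knockout replicate 1 (adjusted p = 0.19), and the basal and periderm calls without E17.5 knockout replicate 2 (0.063 and 0.051) and with no filter on low counts (0.12 and 0.078).

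Stress keratins and alarmins (2 of 17 upward, 1 downward; median 0.64, adjusted p = 0.0024), immediate early and heat shock genes (2 of 13 upward; median 0.69, adjusted p = 0.0010), myeloid markers (4 of 11 upward; median 0.64, adjusted p = 1.4e-08) and muscle markers (1 of 11 upward; median 0.65, adjusted p = 0.00023) differed upward, with Sprr1b at 3.59 ± 0.43, Ier3 at 1.29 ± 0.19 and Lyz2 at 1.31 ± 0.16. The p53 target list (5 of 40 downward; median -0.27, adjusted p = 0.00017), ribosome biogenesis factors (1 of 40 downward; median -0.18, adjusted p = 0.0024), cell cycle genes (0 of 32 called; median -0.37, adjusted p = 7.0e-06) and melanocyte markers (4 of 9 downward; median -0.79, adjusted p = 2.0e-05) differed downward, with Perp at -1.66 ± 0.20. Adjusted over the list alone, the genes upward and downward numbered 10 and 0 for myeloid, 6 and 1 for stress, 3 and 0 for immediate early, 2 and 0 for muscle, 2 and 10 for p53 target, 0 and 1 for biogenesis, 0 and 0 for cell cycle and 0 and 6 for melanocyte genes. None of the 14 list calls held with an estimated correlation. The adjusted p was then 0.16 for myeloid, 0.19 for p53 target, 0.37 for melanocyte, 0.44 for cell cycle and 0.46 for biogenesis genes, and 0.41 for stress, immediate early and muscle genes. Ribosomal protein genes did not pass the test of the difference (median -0.02, adjusted p = 0.48). In the stress and immediate early lists, controls were lower at E17.5, while knockout levels overlapped between the stages. The mean log2 CPM of the immediate early list was 5.56 and 5.87 in E15.5 controls and 5.15 and 5.21 in E17.5 controls. In knockouts it was 5.35 and 5.31 at E15.5 and 5.12 and 5.47 at E17.5. The calls of the stress and immediate early lists were lost without E17.5 knockout replicate 2 (adjusted p = 0.053 and 0.051), and that of the biogenesis factors without E15.5 control replicate 2 (0.075).

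The number of genes called for the difference changed when a library was left out, which leaves 1 library in its group. Such fits have less power, so these counts do not show that the calls rest on particular libraries. The 308 genes with a more positive effect became 184 and 130 without E15.5 control replicates 1 and 2, 122 without E15.5 knockout replicate 2, 175 without E17.5 control replicate 2 and 137 without E17.5 knockout replicate 1, while 201 were left without E15.5 knockout replicate 1. The 403 with a more negative effect became 258 and 268 without E15.5 control replicates 1 and 2, and 255 without E15.5 knockout replicate 2. With library totals as the only scaling the split was 142 against 655.

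**Figure D3:**
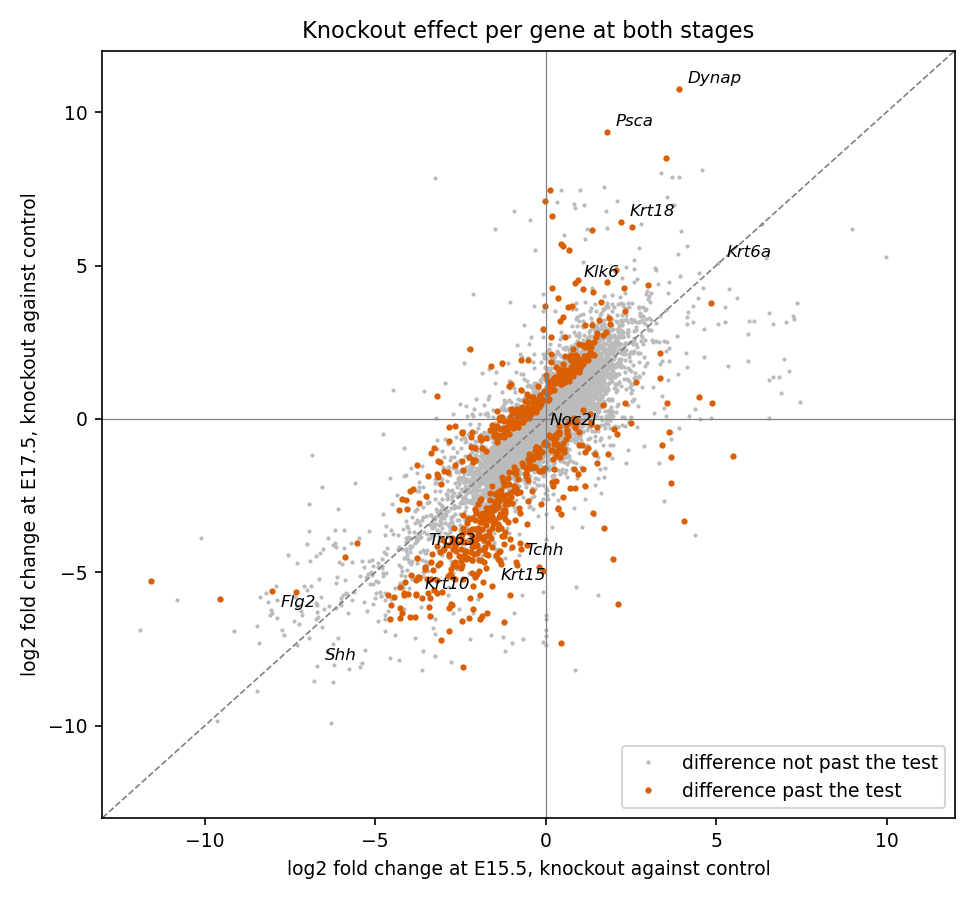
Log2 fold change of each tested gene, knockout against control, at E15.5 (horizontal) and E17.5 (vertical), with genes whose difference between stages passed the test in orange and equal effects on the dashed line. The correlation across the 16342 genes was 0.80, and 711 genes passed the test of the difference.

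The control libraries gave the change from E15.5 to E17.5 in epidermal preparations that also held RNA of other cells. Col1a1 stood at 10865 and 11013 CPM in E15.5 controls and at 8384 and 10055 CPM in E17.5 controls. The change is therefore not that of keratinocytes alone. At the preset correlation hair follicle genes tested upward, with 12 of 24 risen, and granular, cornified and periderm genes downward. With an estimated correlation the follicle call held (adjusted p = 0.023), and the cornified and periderm calls did not (adjusted p = 0.18 and 0.13). Among genes with a mean log2 CPM of at least 1, the adiponectin gene Adipoq rose most (5.79 ± 0.40, adjusted p = 2.0e-05), followed by the follicle keratins Krt75 (5.31 ± 0.27), Krt71 (4.87 ± 0.37), Krt25 (4.61 ± 0.30) and Krt73 (3.73 ± 0.34), the complement gene C3 (3.83 ± 0.34), the haptoglobin gene Hp (3.57 ± 0.32) and the thyrotropin receptor gene Tshr (3.39 ± 0.33). Psca, with 1743 counts at E15.5 and 3 at E17.5 (ratio 650, counting interval 222 to 3154), and Dynap, with 415 and 1 (ratio 464, 82.8 to 18374), fell most, followed by Upk3bl (-6.79 ± 0.47), Upk3b (-6.40 ± 0.40), Msln (-5.46 ± 0.40), Sprr3 (-5.0 ± 0.76), Serpinb9b (-4.98 ± 0.64) and the mucosal keratin Krt13 (-4.92 ± 0.34). In all, 515 genes rose and 1259 fell (10.9% of those tested), 213 and 449 at least 2-fold.

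Several of these sizes rest on single control libraries. Without E15.5 control replicate 1 the change was 4.48 for Krt73 and -5.65 for Sprr3, and without E15.5 control replicate 2 it was -6.12 for Upk3bl, -3.80 for Sprr3 and -4.35 for Serpinb9b. Without E17.5 control replicate 1 it was -7.76 for Dynap and -7.21 for Upk3b, and without E17.5 control replicate 2 it was 5.10 for Adipoq, -10.75 for Dynap, -7.54 for Upk3bl, -6.03 for Sprr3 and -5.81 for Serpinb9b, against a fitted -8.52 for Dynap with all libraries, sizes that depend on the prior count at 1 or 0 E17.5 counts. The counts changed as well when a control library was left out, which leaves 1 library in its group and less power. Genes risen numbered 301, 176 and 186, and genes fallen 924, 490 and 511, without E15.5 control replicate 1, E15.5 control replicate 2 and E17.5 control replicate 2. Both E15.5 control libraries and 1 of the E17.5 control libraries expressed Y-linked genes, and with a term for sex 254 genes rose and 745 fell. With library totals as the only scaling the split was 1486 against 762, with a median of all genes of 0.19.

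Of 37 cornified and granular genes, 28 fell and 2 rose in controls (30 and 3 adjusted over the list alone; median -1.19, camera adjusted p = 6.3e-22, and adjusted p = 0.18 with an estimated correlation). The filaggrin-like gene Hrnr fell from 11566 ± 853 to 2252 ± 967 CPM (-2.36 ± 0.27), Sprr1b by -3.06 ± 0.33 and Lce1c by -1.49 ± 0.18 on the log2 scale. Of 20 spinous genes, 15 fell and 1 rose (16 and 1 adjusted over the list alone; median -0.84, adjusted p = 5.8e-13, and adjusted p = 0.13 with an estimated correlation), with the differentiation regulators Grhl3 (-1.42 ± 0.18) and Ovol1 (-0.85 ± 0.13). Of 21 barrier lipid genes, 16 fell and 2 rose (16 and 3 adjusted over the list alone; median -0.87, adjusted p = 2.7e-12, and adjusted p = 0.18 with an estimated correlation), with Elovl1 (-1.26 ± 0.13) and Dgat2 (-1.01 ± 0.12). Of 10 periderm genes, 7 fell and 1 rose (the same adjusted over the list alone; median -1.39, adjusted p = 7.5e-16, and adjusted p = 0.13 with an estimated correlation), with Krt18 (-3.02 ± 0.19) and Krt6a (-1.80 ± 0.17). Follicle genes moved the other way, 12 of 24 risen and 1 fallen (12 and 3 adjusted over the list alone; median 0.32, adjusted p = 1.2e-18), with Krt27 (5.21 ± 0.20) and Tchh (3.24 ± 0.13), and theirs was the 1 list call of this comparison that held with an estimated correlation (adjusted p = 0.023). Basal genes did not pass (0 of 15 called by edgeR, also adjusted over the list alone; median -0.07).

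Stress keratins and alarmins (6 of 17 fallen, 1 risen, and 9 and 2 adjusted over the list alone; median -0.68, adjusted p = 3.0e-05, and adjusted p = 0.21 with an estimated correlation), immediate early and heat shock genes (5 of 13 fallen, 8 adjusted over the list alone; median -0.46, adjusted p = 3.0e-05, and adjusted p = 0.21 with an estimated correlation) and erythroid markers (7 of 10 fallen, 8 adjusted over the list alone; median -1.59, adjusted p = 2.0e-08, and adjusted p = 0.23 with an estimated correlation) fell in controls, with Hspa1a at -1.08 ± 0.16, Hspa1b at -1.04 ± 0.14 and Hba-a1 at -1.58 ± 0.25. Melanocyte markers rose (4 of 9, with 1 fallen, the same adjusted over the list alone; median 0.38, adjusted p = 0.00073, and adjusted p = 0.35 with an estimated correlation). Ribosome biogenesis factors and cell cycle genes tested upward with 0 called members each (medians 0.12 and 0.13, adjusted p = 0.010 for both, and adjusted p = 0.56 and 0.67 with an estimated correlation). Both calls were lost without E15.5 control replicate 2 (adjusted p = 0.20 for both), and that of the biogenesis factors without E17.5 control replicate 1 (0.094). The remaining lists did not pass. Their medians were -0.22 for endothelial, 0.18 for myeloid and 0.01 for fibroblast markers.

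The knockout effect at E17.5 was set against the change in controls from E15.5 to E17.5, to ask whether they go together. Across 16342 genes these correlated at r = -0.066 (rho -0.046), with a covariance of -0.0472. Both use the E17.5 control libraries with opposite sign, so chance alone gives a negative relation. In 100 simulations with knockout libraries drawn at the control means, r averaged -0.21 (lowest -0.245) and the covariance -0.0353 (lowest -0.0416). The observed covariance differed from the simulated mean by -0.0119 and lay below the lowest of the 100 draws. The observed r was nearer 0 than the simulated mean, but these values of r are not comparable. The simulated knockouts had no effect of their own, so their fold changes spread less. For the same covariance, r then lies further from 0. No direction beyond the shared controls is drawn, since the covariance changed sign with the genes included. Among genes with a mean log2 CPM of at least 1, r was 0.0507 and the covariance 0.0260, so the sign of the raw values depends on the genes included. The simulations covered all 16342 genes only, so the values of this subset have no simulated value beside them. The controls were not split, since each part would hold 1 library. The part that comes from the shared controls is thus known from the simulations only, at -0.0353 against the observed covariance of -0.0472.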

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

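The test of a difference between the stages was planned, and the tests used to weigh explanations were chosen only after the results were seen. The results in this part stand out because the knockout effect passed the test of a difference between E17.5 and E15.5. Of the 123 genes looked at, 48 did so, 31 downward and 17 upward, and 14 lists did. Some of these genes were named because they passed this same test, so their share is raised by the choice. Over all 16342 genes, 4.35% passed. Of the 14 list calls, 0 held with an estimated correlation and 4 with fry.

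Some single genes were further below control at E17.5 than at E15.5. The differences were -5.67 and -3.88 for the keratins Krt27 and Krt15, -3.79 for the trichohyalin gene Tchh and -2.95 for the transcription factor gene Msx2. Krt27, Tchh and Msx2 were higher in E17.5 than in E15.5 controls. Krt27 went from 2.08 and 1.46 to 59.4 and 71.8 CPM in controls, and from 0.407 and 0.246 to 0.256 and 0.216 CPM in knockouts. Krt15 was lower in E17.5 than in E15.5 knockouts (21.8 and 17.8 against 215 and 283 CPM). Krt75, a follicle keratin, reversed, with a difference of -4.28: it rose at E15.5 (3.42, adjusted p = 3.0e-06) and fell at E17.5 (-0.86, adjusted p = 0.0034). Its level was higher at E17.5 in both genotypes, more so in controls. Controls went from 0.755 and 0.845 to 25.8 and 37.9 CPM, and knockouts from 8.99 and 8.23 to 14.9 and 20.3 CPM. Hp and Adipoq likewise rose in both genotypes. Hp went from 2.23 and 1.19 to 14.8 and 25.9 CPM in controls, and from 3.52 and 3.24 to 11.4 and 11.4 CPM in knockouts. Among genes of the differentiating layers the differences were -3.32 for Dlx3, -3.30 for Hrnr, -2.78 for Lor, -2.43 for Lce1c, -2.17 for Zfp750, -2.01 for Klk5, -2.00 for Dmkn, -1.93 for Krt10, -1.93 for Evpl, -1.78 for Krtdap, -1.66 for Perp, -1.45 for Dsg1a and -1.37 for Ovol1. Barrier lipid genes Cyp4f39 (-2.03), Alox12b (-1.98) and Dgat2 (-1.22), basal genes Krt5 (-1.45) and Cdh3 (-1.24), and Aox4 (-4.11) and Serpinb7 (-3.30) differed in the same direction. The adipocyte gene Adipoq differed by -3.12 (-2.43 without E17.5 control replicate 2), and P2ry4 by -4.08 (-8.19 without E17.5 knockout replicate 1, which leaves 0 knockout counts, and -3.13 without replicate 2).

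Many upward differences were in genes nearly silent in E17.5 controls: 7.55 for Psca and 6.83 for Dynap, fitted values that depend on the prior count with 3 and 1 control counts, 5.26 for Upk3b, 4.997 for Serpinb9b, 4.80 for Upk3bl and 3.72 for Msln. All were higher in E15.5 than in E17.5 controls. Apart from Serpinb9b, they were also lower in E17.5 than in E15.5 knockouts, so the differences do not show a stronger late induction. Psca went from 25.1 and 41.4 to 0.0362 and 0.0642 CPM in controls, and from 102 and 129 to 28.4 and 44.1 CPM in knockouts. Dynap gave 6.06 without E17.5 control replicate 1 and 9.06 without replicate 2, which leaves 0 control counts, Upk3b 6.07 without E17.5 control replicate 1, and Serpinb9b and Upk3bl 4.36 and 4.14 without E15.5 control replicate 2 and 5.83 and 5.56 without E17.5 control replicate 2. Differences were also upward for the keratins Krt18 (4.20), Krt13 (2.99) and Krt8 (1.36). Krt13 was lower at E17.5 in both genotypes, more so in controls. Other upward differences were 3.59 for Sprr1b, 3.57 for Klk6, 3.11 for Ccl6, 2.42 for Serpinb3a, 1.31 for Lyz2, 1.29 for Ier3 and 1.14 for Nupr1.

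With limma-voom the difference did not pass for Dynap (adjusted p = 0.051), Serpinb3a (0.089), P2ry4 (0.078) and Adipoq (0.107). The calls of 5 genes were lost with limma-voom and also when single libraries were left out. Krt6b (-1.07) lost it without any library other than E15.5 control replicate 1 and E17.5 knockout replicate 2, and Hp (-1.82), which rose at E15.5 (0.98) and fell at E17.5 (-0.84), without any other than replicate 1 of the control groups. Trp73 (-1.53) lost it without E15.5 control replicate 2 (adjusted p = 0.069), E15.5 knockout replicate 1 (0.057) or 2 (0.091), E17.5 control replicate 2 (0.066) or E17.5 knockout replicate 1 (0.14). Serpinb3c (3.68) lost it without E15.5 knockout replicate 2 (3.12) or E17.5 knockout replicate 1 (2.77), and gave 4.47 without E15.5 knockout replicate 1. Tshr (-2.41) lost it without E15.5 control replicate 2 (-2.17), E15.5 knockout replicate 1 (-1.84), E17.5 control replicate 2 (-2.13) or E17.5 knockout replicate 2 (-2.22).

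The lists with a difference between the stages, by median, were barrier lipid (-0.94), melanocyte (-0.79), spinous (-0.57), follicle (-0.51), cell cycle (-0.37), p53 target (-0.27), cornified (-0.22) and ribosome biogenesis (-0.18) genes, then immediate early (0.69), muscle (0.65), myeloid (0.64) and stress (0.64) genes. The basal (0.0356) and periderm (-0.0360) medians have the opposite sign to their tests. In addition, transcripts without a gene name held 2.24% of counts in E15.5 knockout and 2.58% in E17.5 knockout libraries against 1.505% and 1.912% in controls, a difference that was not tested, and they are not analysed here.

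Keratinocyte genes were lower in knockout libraries, and a lower share of keratinocytes might be the cause. A lower share alone would move genes expressed only in keratinocytes by a similar amount. The interquartile range of the log2 fold changes of the 93 keratinocyte list genes was 1.51 at E15.5 and 2.56 at E17.5. Their median SEs were 0.186 and 0.208, so these genes did not move by 1 common factor. The lists join several layers and were not checked for expression in other cells, so unequal falls do not exclude a lower share. Markers of other cells did not rise alike either. The fibroblast median lay 0.61 above the endothelial median at E15.5 (permutation p = 0.0141) and 0.59 above it at E17.5 (permutation p = 0.0294). That permutation shuffled genes, which are not independent, and it does not measure the keratinocyte share. Scaling moves every gene alike. The keratinocyte median lay at -1.90 at E15.5 and -2.61 at E17.5 from the median of all genes. Random sets of 93 genes reached no lower than -0.292 and -0.306 (permutation p = 1.0e-04 for both). With the median of all genes near 0, these distances restate the fall of the lists. With library totals as the only scaling, 82 of these genes fell at E15.5 and 79 at E17.5. With TMM the numbers were 82 and 77, so scaling is argued against as the cause. A loss of differentiated keratinocytes alone is argued against by basal medians of -1.91 at E15.5 and -2.03 at E17.5. A lower share of keratinocytes, as the cause or as a part of it, remains open.

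Noc2l itself changed little in knockout libraries. A single mislabelled library is argued against, since 0 of the 8 libraries correlated best with the other genotype. RNA of cells outside the Krt14 lineage could hold up the level (log2 fold change -0.12 at E15.5), as could reads from exons that the deletion leaves, because there is 1 count per library for the whole transcript. These explanations cannot be told apart here.

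Granular and cornified genes were lower at E17.5 in controls, although the barrier forms between these stages. Exchanged stage labels could give this, but 12 follicle list genes were higher at E17.5 and 1 was lower, which argues against it. A lower share of all keratinocyte layers alike is argued against by the basal median, 1.11 above the cornified median (permutation p = 0.00244). That permutation shuffled genes, which are not independent. Sex is argued against as well, since 89.3% of the fallen cornified list genes (25 of 28) were still fallen with a term for sex. Basal genes would not show a lower share of the differentiated layers alone, so that explanation remains open.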

How the results depend on the processing

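The alternatives fixed before the data were examined are named in the description of the processing, and the tests with library totals, a term for sex and other transcript choices were chosen only after the result was seen. No result changed direction with a call in both settings. With a log2 fold change of at least 1, genes risen and fallen numbered 1434 and 1545 at E15.5, 2192 and 1774 at E17.5 and 213 and 449 in controls, and 153 genes had a more positive effect at E17.5, because the threshold removes smaller changes. Lists called with an estimated correlation numbered 2, 2, 0 and 1 against 15, 15, 14 and 11, and 4 of the 14 for the difference were called with fry, which also lost 2 in controls. Fry also called lists that camera did not. At E15.5 and E17.5 its adjusted p was 0.00058 and 0.00092 for amino acid response genes (downward). It was 0.0061 and 0.0096 for apoptosis genes and 0.0026 and 0.0014 for Schwann cell and neuron markers (both upward). At E15.5 fry also called ribosome biogenesis factors (adjusted p = 0.015) and immediate early and heat shock genes (0.018), both downward. At E17.5 it also called Merkel cell markers (0.0019, downward) and melanocyte markers (0.048, upward). In controls it added T cell markers (0.015, upward). Amino acid response genes (0.015), endothelial markers (0.025) and Merkel cell markers (0.047) were added downward. With no low-count filter and with a replicate block the basal and periderm calls for the difference were lost (2 each).

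For the difference between stages, the 308 genes upward became 509 with DESeq2, 524 with a replicate block, 142 with library totals and 122 to 353 when each library was left out, and the 403 downward became 655 with library totals and 255 to 392. In controls the 515 risen became 1486 with library totals, 254 with a term for sex and 176 to 521, and the 1259 fallen became 762, 745 and 490 to 1255. Library totals shift all genes together, and leaving out a library leaves 1 in its group, which was taken to vary like the other groups. For the other settings the cause was not tested. The correlation of the knockout effects (0.80) was 0.735 to 0.772 when a library was left out. The relation of the knockout with development was r = 0.0507 and covariance 0.0260 at the higher expression minimum.

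Replicate numbers were treated as names, since the labels do not tie them and 2 per group are too few to settle it: differences between replicates correlated at 0.126 and 0.130 between genotypes and -0.0544 between control stages over 13569 genes. The fit to only the groups compared does not apply to the difference. Of 711 genes called for it, 581 were also called with limma-voom and 700 with DESeq2, and of 1774 called in controls 985 with a term for sex.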

Other observations

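The gene groups of this part and their tests were chosen only after the knockout values had been seen, except the sex-linked genes, so their p-values describe and do not test. Interferon-stimulated genes rose in knockout epidermis at both stages, 19 of 22 at E15.5 (20 adjusted over the list alone; median log2 fold change 1.42, camera adjusted p = 5.0e-07, and adjusted p = 0.16 with an estimated correlation) and 22 of 22 at E17.5 (median 2.37, adjusted p = 6.9e-12, and adjusted p = 0.075 with an estimated correlation). The antiviral gene Rsad2 changed by 2.85 ± 0.21 and 2.43 ± 0.20, Oas2 by 1.82 ± 0.16 and 2.53 ± 0.15, and the RNA sensor genes Ddx58 by 1.49 ± 0.14 and 2.01 ± 0.14 and Ifih1 by 0.78 ± 0.17 and 1.90 ± 0.17. Myeloid markers rose in the same libraries (medians 1.17 and 1.93).

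Of 6 simple epithelial keratins, 4 rose and 2 fell at E15.5 and 4 rose and 1 fell at E17.5, the same adjusted over the list alone (medians 2.14 and 3.75, adjusted p = 8.0e-05 and 7.0e-06, and adjusted p = 0.107 and 0.075 with an estimated correlation), with Krt7 at 2.05 ± 0.31 and 4.84 ± 0.37 and Krt19 at 3.23 ± 0.24 and 3.13 ± 0.26 at E15.5 and E17.5. Epithelial transcription factors and splicing regulators fell, 10 of 12 at both stages with 1 risen at E15.5, and adjusted over the list alone 10 fallen and 1 risen at both (medians -2.67 and -3.78, adjusted p = 7.7e-17 and 5.0e-24), among them Irx4 (-4.56 and -6.51), Gata3 (-3.26 and -5.57), Tfap2c (-2.85 and -4.47), Grhl2 (-2.83 and -4.41) and Esrp1 (-2.64 and -4.79). With an estimated correlation the adjusted p was 0.077 and 0.046. Of 12 epithelial adhesion genes, 8 fell and 1 rose at E15.5 (9 and 1 adjusted over the list alone) and 10 fell and 2 rose at E17.5 (the same adjusted over the list alone), with medians of -1.65 and -2.34 (adjusted p = 2.0e-07 and 6.3e-11, and adjusted p = 0.107 and 0.075 with an estimated correlation). Among them the E-cadherin gene Cdh1 fell from 333 to 83.8 CPM at E15.5 and from 266 to 38.8 CPM at E17.5. All 10 measured imprinted growth genes rose at both stages (medians 1.02 and 1.25, adjusted p = 5.0e-07 and 6.5e-08, and 0.11 and 0.075 with an estimated correlation), with Peg3 at 1.33 ± 0.12 and 1.59 ± 0.12 and Igf2 at 1.01 ± 0.14 and 1.45 ± 0.14, in libraries where fibroblast markers also rose (medians 1.23 and 1.39). Hmox1 fell at E15.5 (-0.56, adjusted p = 0.037) and rose at E17.5 (0.82, adjusted p = 0.0047).

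Y-linked transcripts summed to 160 and 165 CPM in the E15.5 control and 150 and 161 CPM in the E15.5 knockout libraries, with Xist at 0.0377, 1.69, 0.518 and 0.774 CPM. At E17.5 they summed to 143 and 0.193 CPM in controls and 0.475 and 128 CPM in knockouts, with Xist at 0.616, 1196, 1256 and 29.3 CPM. Each E17.5 group thus holds a library with Y-linked expression and a library with Xist and hardly any Y-linked expression. E17.5 knockout replicate 2 had Y-linked expression together with Xist at 29.3 CPM, where other libraries with Y-linked expression had at most 1.69 CPM. The term for sex grouped it with those libraries.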
